A study of Mus musculus with 6 samples.

How the data were processed

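Gene expression was measured on Affymetrix mouse arrays in cells sorted from the left ventricle of male Black Swiss mice aged 8 to 10 weeks. Per the labels, 3 mice had transverse aortic constriction (TAC), a surgical narrowing of the aorta that overloads the left ventricle with pressure, and 3 mice had a sham operation, and cells were isolated 1 week later. From each surgery came 3 cell populations: cardiac fibroblasts traced by Tie2-Cre, untraced cardiac fibroblasts, and endothelial cells. Tie2-Cre is a Cre recombinase under the promoter of the endothelial receptor gene Tek, so that tracing marks cells that have, or whose ancestors had, an active Tek promoter. Labelling started from 200 ng of total RNA per sample, per the labels' protocols. The labels give 6 groups with 1 array each. They do not say whether the arrays of 1 surgery came from the same hearts, or whether the RNA of 3 mice was pooled, so no array was treated as a replicate of another in comparisons of surgery or lineage.

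The deposited values are probe set intensity values for 45101 probe sets on each of the 6 arrays, with no missing values. The submitters' processing notes name RMA, a method that subtracts background, normalizes arrays to the same distribution and summarises probes on a log2 scale. The version of RMA and the software that ran it are not given in the sources used here. The deposited intensity values lie between 3.82 and 37205, so they are on a linear scale, and the step back from log2 is read from the values and not stated. Array medians lay between 106.6 and 115.2 intensity units, and quartiles were also close, as between-array normalization leaves them. No further normalization was applied, and log2 of the intensity was taken before any comparison. RMA pulls differences of dim probe sets towards 0 and gives no detection call. For arrays the number of arrays limits the precision, and with 1 array per group a difference between 2 arrays has no error of its own. All pairs of arrays were compared and 0 pairs held identical values.

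Gene names came from the platform annotation, updated by gene identifier to current symbols, with 99.4% of identifiers of probe sets with 1 symbol found in the reference gene table. Of the probe sets, 34958 had exactly 1 symbol, 932 had several and 9211 were not listed with a gene and are unnamed here. Each of the 18194 genes was represented by the probe set with the highest mean over the 6 arrays among those with exactly 1 symbol, and 9012 genes had several probe sets. A gene counted as detected when it lay above the median of its own array on at least 1 of the arrays compared. This left 12257 genes over the 6 arrays, 11623 over the 4 fibroblast arrays and 11157 over the 2 endothelial arrays.

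Fibroblasts and endothelial cells were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) after the traced and untraced arrays of 1 surgery had been averaged, so that each cell type had 2 values, 1 per surgery, and 2 residual degrees of freedom remained. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 with at least a 2-fold difference. The p-values measure only the spread between these samples, which here is the difference between surgeries, and that spread may be partly technical. The fit was tested on simulated data for 12257 genes: of 50 genes changed in each size class, it called 3 at a log2 change of 1, 37 at 2, 47 at 4 and 47 at 6, and it called 8 unchanged genes. The simulated arrays had independent noise with the spread of the fibroblast arrays. They lack the surgery effect that traced and untraced arrays share, so these numbers may overstate how well the fit works here.

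All other comparisons set 1 array against 1 and were not tested. For them the text counts genes with at least a 2-fold difference in the same direction in both fibroblast populations, at both surgeries or in all 3 populations. The count that unrelated differences would give came from 1000 shuffles of the genes within 20 bins of mean expression. On simulated data for 11623 genes, the count of unrelated genes was 31 against a shuffled mean of 25, and 200 of 200 genes raised 4-fold in both were found. The difference between the TAC responses of traced and untraced fibroblasts was divided by 2. If the errors of the 4 fibroblast arrays are independent, it then has the same technical error as the mean TAC and mean lineage differences. On that condition it serves as a yardstick for both. Errors that the arrays of 1 surgery share cancel in it but stay in the mean TAC difference, so it can understate the error there. For the difference of responses, a gene was counted when its responses differed at least 4-fold.

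A total of 38 gene lists with 668 entries was written from textbook knowledge, covering cell type markers and pathways of the heart. For each list with at least 3 detected members, the median log2 difference is given with its percentile among 10000 random lists of the same size matched on mean expression. This describes the arrays and is not a test over replicates. Genes restricted to fibroblasts were compared with genes drawn 1000 times from 20 bins of the endothelial sham level. The fibroblast share of a gene is its rise on the endothelial TAC array over the endothelial sham array, as a percent of the excess of the fibroblast TAC intensity over the endothelial sham intensity, and a net share counts only the rise beyond that of the drawn genes. On simulated data 2.5% of 40 unchanged lists lay outside the middle 95% of the random lists. The simulated genes varied independently, while genes of a real list may vary together. This percent therefore does not show how often real lists lie outside the middle 95% without an effect.

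The lists, the designs, the thresholds and the rule for naming genes were fixed before the data were examined. The rule named the 8 genes per direction with the largest difference between fibroblasts and endothelial cells, the 10 per direction for TAC in fibroblasts, for lineage and for TAC in endothelial cells, the 5 per direction for the difference of responses, up to 4 members per list described, and in all cases Tek, Pecam1, Cdh5, Pdgfra, Col1a1, Col1a2, Postn and Acta2. Genes with provisional names stayed in the counts and were not named. Alternatives were a repeated quantile normalization, centring each array on its median, the mean of all probe sets of a gene, no filter or a stricter filter on dim genes, other fold thresholds, leaving out probe sets whose suffix marks possible cross-hybridisation, other limma designs, and leaving out each array. Alternatives chosen after seeing the data were each fibroblast population alone, each surgery alone, and the endothelial TAC array after an estimated share of fibroblast RNA had been taken off. Scores of lists and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Scanner files, a genome sequence and coordinates were not used here.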

Results

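The data are 6 array profiles of cells from the left ventricle, 1 each of traced fibroblasts, untraced fibroblasts and endothelial cells from sham operated mice and from mice with TAC, and none of these groups has a replicate. All levels and differences below are on the log2 scale of the probe set intensity unless a fold is given. Across the 45101 probe sets, traced and untraced fibroblasts of the same surgery correlated at 0.991 at sham and 0.991 after TAC, and sham and TAC endothelial cells at 0.966. The fibroblast arrays of both surgeries correlated with the endothelial sham array at 0.848 to 0.873. With the endothelial TAC array they correlated at 0.909 to 0.917. Correlations across genes or probe sets describe the arrays, since genes are not independent replicates.

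The first comparison asks how far the sorted cells carry the profiles of fibroblasts and of endothelial cells. Endothelial arrays carried the endothelial junction genes Pecam1 and Cdh5 at 64.6-fold and 82.2-fold the fibroblast level, and fibroblast arrays carried the fibroblast receptor gene Pdgfra at 17.7-fold the endothelial level. In all, 1415 genes were higher in fibroblasts and 797 in endothelial cells among 12257 genes (limma, Benjamini-Hochberg). Spike-in controls also stood higher on the endothelial arrays, so a technical difference runs along with cell type here. The largest endothelial differences were those of Car4, a carbonic anhydrase of capillary endothelium (165-fold), Aqp7, a glycerol channel (159-fold), Myct1 (131-fold), the endothelial receptor kinase Tie1 (127-fold), Cd300lg (120-fold), the sphingosine phosphate receptor S1pr1 (117-fold), Rasgrp3 (112-fold) and the guidance receptor Robo4 (110-fold). The largest fibroblast differences were those of the matrix protein gene Efemp1 (92.3-fold), the ferritin receptor gene Scara5 (69.5-fold), the potassium channel gene Kcnt2 (59.5-fold), the secreted semaphorin Sema3c (57.2-fold), the matricellular gene Smoc2 (50.2-fold), Cyp1b1 (49.6-fold), Pxylp1 (47.4-fold) and proenkephalin, Penk (44-fold).

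The difference for Pecam1 was -6.01 with a standard error of 0.396 (limma adjusted p = 0.00465, 2 values per cell type), that for Cdh5 was -6.36 with a standard error of 0.313 (limma adjusted p = 0.00382), and that for Pdgfra was 4.15 with a standard error of 0.448 (limma adjusted p = 0.0103). Tek, whose promoter drives the Cre, did not pass: it stood at 10.70 to 11.90 on the fibroblast arrays and at 12.38 to 12.63 on the endothelial arrays, a difference of -1.13 (limma adjusted p = 0.109). The collagen genes Col1a1 (3.02, limma adjusted p = 0.223) and Col1a2 (2.88, limma adjusted p = 0.238) and the matricellular gene Postn (3.29, limma adjusted p = 0.281) did not pass either, and each stood more than 4 log2 units higher on the endothelial TAC array than on the endothelial sham array. Acta2, the smooth muscle actin gene, differed by 0.19 (limma adjusted p = 0.842). Without the endothelial sham array 685 genes were higher in fibroblasts and 472 in endothelial cells, and Efemp1, Scara5 and Penk no longer passed. Penk also lost its call without the endothelial TAC array. With surgery as a block 2298 genes were higher in fibroblasts and 1114 in endothelial cells, and Tek then passed, while Col1a1, Col1a2, Postn and Acta2 did not. On at least 1 array of the cell type in which they were lower, Aqp7, Cd300lg, Kcnt2, Pxylp1 and Tbx18 stood below the 10th percentile of that array, so the sizes of their differences rest on dim values.

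**Figure D1:**
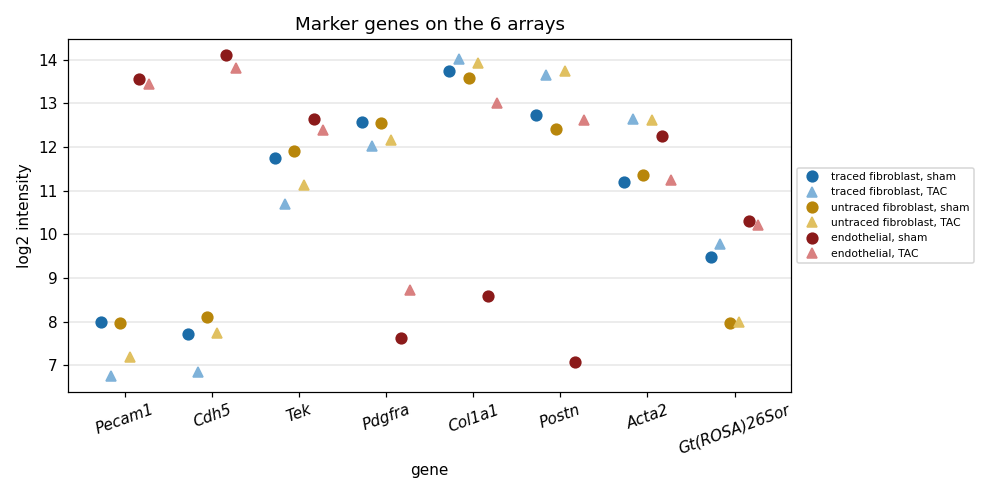
Log2 intensity (vertical axis) of 8 genes on the 6 arrays, each point 1 array, circles sham and triangles TAC, with no error bars because each group has 1 array. Pecam1 and Cdh5 stand above 13 on both endothelial arrays and at or below 8.10 on all fibroblast arrays, while Postn stands at 7.07 on the endothelial sham array and at 12.62 on the endothelial TAC array.

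Of 25 detected endothelial markers 23 were higher in endothelial cells over all genes and 25 adjusted over the list alone, with a median difference of -5.88. Emcn, a mucin of capillary and venous endothelium, differed by -6.71 and the transcription factor gene Sox17 by -6.56. Of 12 genes in the list of capillary fatty acid handling 10 were higher in endothelial cells and 11 adjusted over the list alone, among them Gpihbp1, which holds lipoprotein lipase on capillaries (-6.45), Timp4 (-6.48) and the retinol binding protein gene Rbp7 (-5.96). Of 11 arterial genes 8 were higher in endothelial cells, and also 8 adjusted over the list alone, such as the Notch ligand gene Dll4 (-4.58), Efnb2 (-4.38) and the gap junction gene Gja5 (-3.69). Of 17 genes of angiogenesis 7 were higher in endothelial cells and 10 adjusted over the list alone, including Trp53i11 (-4.68) and the chemokine receptor gene Cxcr4 (-4.14). Of 16 interferon response genes 5 were higher in endothelial cells and 8 adjusted over the list alone, with Rsad2 at -4.19 and Oas1a at -2.27. The transcription factor gene Wt1, listed here as an epicardial marker, was higher in endothelial cells (-4.89, limma adjusted p = 0.00466).

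Of 20 detected fibroblast markers 8 were higher in fibroblasts over all genes and 15 adjusted over the list alone, with a median of 3.85, for example the transcription factor gene Tcf21 (4.86), Islr (5.01) and the collagen receptor gene Ddr2 (4.08). Of 26 growth factor and receptor genes 10 were higher in fibroblasts and 3 in endothelial cells, and 12 and 3 adjusted over the list alone, with Angptl1 (4.83) and Igfbp6 (4.85) on the fibroblast side and Pdgfb (-5.39) on the endothelial side. Of 21 cytokine genes 7 were higher in fibroblasts and 1 in endothelial cells, the same numbers adjusted over the list alone, including the chemokine genes Ccl7 (5.06) and Cxcl14 (4.79) and the alarmin gene Il33 (4.78). Of 15 cardiogenic transcription factor genes 7 were higher in fibroblasts and 3 in endothelial cells, and 9 and 3 adjusted over the list alone, with Tbx18 at 4.76 and Tbx3 at -4.60. Of 18 collagen and crosslinking genes 1 was higher in fibroblasts (1 adjusted over the list alone), Col5a3 at 4.31, and of 30 other matrix genes 5 were (5 adjusted over the list alone). Their median differences were still 2.85 and 3.56 in favour of fibroblasts. The medians of both lists stood 2.60 and 3.05 higher on the endothelial TAC array than at sham, and this enters the spread that the p-values measure. Few calls here therefore do not mean small differences. Cardiomyocyte markers were higher in endothelial cells for 5 of 12 (9 adjusted over the list alone), with Myl2 at -2.74 and Actc1 at -2.79.

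The second comparison asks how the fibroblasts of TAC mice differed from those of sham mice after 1 week. The fibroblasts after TAC had higher levels of the proliferation list and of the matrix lists, while the list of fibroblast markers stayed near 0. Wfdc18 stood 28.6-fold higher on average, the fibrillar collagen gene Col11a1 27.7-fold, the matricellular gene Ccn4 21.5-fold and Cthrc1, a secreted collagen triple helix protein, 19.6-fold. Penk stood 9.43-fold lower, the anion transporter gene Slco2b1 10.2-fold lower and the eotaxin gene Ccl11 8.04-fold lower. Of 11623 genes 503 were at least 2-fold higher in both populations and 208 at least 2-fold lower, against shuffled means of 59.8 and 13 and highest shuffled counts of 78 and 25. Both populations of a surgery may come from the same mice. Neither their agreement nor the shuffles can therefore tell TAC from other differences between the mice or their processing.

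Among the other genes with the largest mean differences were Depdc1a (4.10), Ect2 (4.04) and Cep55 (3.92), which act in mitosis and cytokinesis, C1qtnf3 (4.08), Klrb1a (3.90) and the kinesin family gene Kif26b (3.88). On the lower side were neuromedin B, Nmb (-3.32), the carboxylesterase gene Ces1d (-3.27), the methyltransferase gene Inmt (-3.23), Galnt15 (-3.20), periplakin, Ppl (-3.18), the vasopressin receptor gene Avpr1a (-2.89) and the transcription factor gene Zbtb16 (-2.87). The TAC differences of the traced and untraced fibroblasts correlated at 0.873 across 11623 genes and shared their sign in 76.7% of genes. The standard deviation across genes was 0.621 for the mean TAC difference and 0.162 for the difference between responses, and 904 genes against 3 reached 2-fold on these scales. Errors shared by the arrays of 1 surgery stay in the mean TAC difference and cancel in the difference between responses. The gap may therefore overstate how far TAC stands above error. No difference of this comparison was tested, since each population has 1 array per surgery, and Depdc1a and Ect2 stood below the 10th percentile of at least 1 sham array, so their sizes rest on dim values. The untraced TAC array, which enters these counts, had 18S ribosomal RNA at 12.04 against 14.11 to 14.64 on the other arrays. Without the untraced arrays 720 genes were at least 2-fold higher and 309 lower in traced fibroblasts alone. With fewer conditions to meet, these counts cannot fall below those of both populations.

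**Figure D2:**
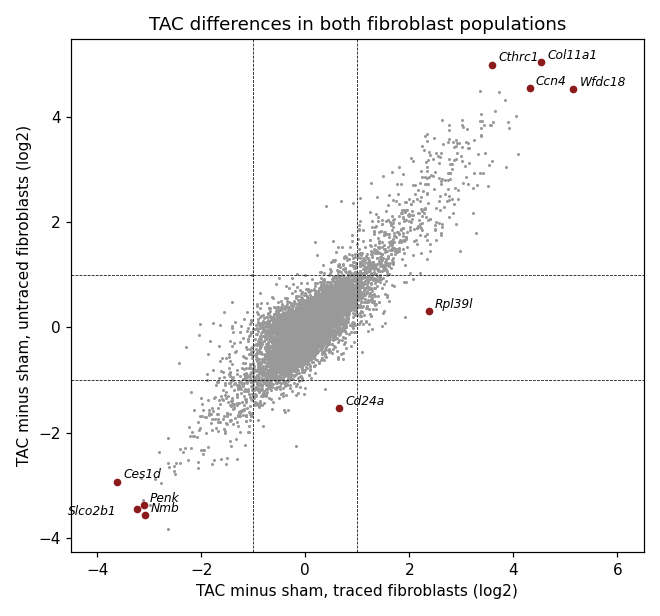
TAC minus sham in traced fibroblasts (horizontal axis, log2) and untraced fibroblasts (vertical axis, log2) for the 12257 genes detected on at least 1 of the 6 arrays, each grey point 1 gene, dashed lines at a 2-fold difference. The 10 genes marked in red are the 4 with the largest mean difference in each direction and Cd24a and Rpl39l, whose responses differed most between the populations and the differences on both axes correlate at 0.873 over the 11623 genes detected on the fibroblast arrays.

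Of 29 detected proliferation genes 27 were at least 2-fold higher in both populations, with a median of 2.92 and a place above all of 10000 random lists. Bub1, a mitotic checkpoint kinase gene, was 3.71 higher, the mitotic kinase gene Pbk 3.59, topoisomerase Top2a 3.52 and Cdk1 3.50. Of 30 other matrix genes 12 were at least 2-fold higher and 1 lower (median 0.83, percentile 100), among them the tenascin gene Tnc, Cthrc1 (4.29), Thbs4 (3.18) and Col12a1 (2.94), and Postn was 1.12 higher. Of 18 collagen and crosslinking genes 5 were at least 2-fold higher (median 0.37, percentile 100), among them P4ha3 (3.66), the lysyl oxidase gene Lox (2.66) and Plod2 (1.66), which modify or crosslink collagen. The abundant collagen genes moved less: Col1a1 was 0.30 higher, Col1a2 0.41 higher and Col3a1 0.04 higher. Of 12 contractile genes 4 were at least 2-fold higher (median 0.49, percentile 100): Tagln (2.19), Actn1 (2.06), the transcription factor gene Meox1 (1.88) and Acta2 (1.35). The Acta2 value rests on a probe set whose suffix marks possible cross-hybridisation, and it was -0.215 without such probe sets and 0.297 with the mean of all its probe sets.

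Of 19 TGF-beta response genes 2 were at least 2-fold higher (median 0.45, percentile 100), thrombospondin Thbs1 (1.74) and the oxidase gene Nox4 (1.68 in traced and 1.32 in untraced fibroblasts). Of 17 proteases and inhibitors 4 were at least 2-fold higher (median 0.30, percentile 99.62), with Adam12 at 2.77, Timp1 at 2.05 and Adamts4 at 1.63. Of 19 cytokine genes 7 were at least 2-fold higher and 2 lower (median 0.44, percentile 99.86), with Cxcl2 at 3.45, Il6 at 3.31 and Cxcl10 at 2.69 above and Ccl11 at -3.01 below. The median of 18 immediate early genes, which also respond to cell isolation, was 0.20 (percentile 99.65), with 0.11 in traced and 0.28 in untraced fibroblasts and with Egr2 at 1.80 and Ier3 at 1.15. The median of 16 interferon response genes was 0.42 (percentile 99.9), with Rsad2 at 1.73 and Usp18 at 1.48, and that of 18 hypoxia and glycolysis genes was 0.36 (percentile 99.99), with Pgk1 at 0.78 and Ldha at 0.72. Of 14 genes of mesenchymal transition 4 were at least 2-fold higher (median 0.23, percentile 95.56), among them the cadherin genes Cdh2 (2.54) and Cdh11 (2.01) and fibronectin, Fn1 (1.82).

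The 20 fibroblast markers as a list stayed near 0 (median 0.02, percentile 49.32), with Pdgfra at -0.47 and Tcf21 at -0.59. The median of 20 genes of protein folding stress was -0.25 (percentile 0.02), with Sdf2l1 at -1.74 and Trib3 at -1.19 and with Chac1 at 1.47 in the other direction. Markers of other cells also differed between the surgeries. The 21 detected endothelial markers had a median of -0.55 (below all random lists), with Kdr at -1.29, Pecam1 at -1.22 in traced and -0.78 in untraced fibroblasts, Tek at -0.91 and Cdh5 at -0.63, although Ecscr (2.77), Erg (1.71) and Ptprb (1.40) were at least 2-fold higher in both populations. Over genes above the upper quartile of an array, this median was 0.584. The 11 mural cell markers had a median of -0.57 (percentile 0.01), with Vtn at -2.06 and Myh11 at -1.81 but Mcam 4.01-fold higher, and 9 macrophage markers a median of -0.49 (percentile 0.18), with Cx3cr1 at -1.74 and Csf1r at 1.20. In all, 19 of 35 lists lay outside the middle 95% of their random lists.

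The third comparison asks whether fibroblasts traced by Tie2-Cre differ from untraced fibroblasts. They were nearly alike: of 11623 genes 4 were at least 2-fold higher in traced fibroblasts at both surgeries and 4 at least 2-fold lower, against a shuffled mean of 0.3 and a highest shuffled count of 3 in each direction. The largest difference was that of Gt(ROSA)26Sor, the transcript of the Rosa26 locus, where Cre reporters are often placed, which stood 3.15-fold higher in traced fibroblasts, by 1.52 at sham and 1.79 after TAC. The homeobox gene Msx1 was 1.39 and 1.08 higher and the immunoglobulin family gene Igsf6 1.14 and 1.08 higher. Lower in traced fibroblasts were the cell adhesion gene Chl1 (-1.65 and -1.54), the T cell costimulation gene Cd28 (-1.91 and -1.22), synapsin, Syn2 (-1.45 and -1.04), and the homeobox gene Zfhx4 (-1.06 and -1.17). A further gene higher in traced fibroblasts has a provisional name. Other probe sets gave smaller mean differences for Msx1 (0.77 against 1.23) and Syn2 (-0.67 against -1.25).

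The genes that mark the cell types and the scar response differed little by lineage: Tek was -0.15 at sham and -0.44 after TAC, Pdgfra 0.00 and -0.13, Col1a1 0.17 and 0.09, Col1a2 -0.07 and -0.13, Postn 0.33 and -0.08, and Acta2 -0.16 and 0.03, in traced minus untraced fibroblasts. Pecam1 was 0.02 and -0.42 and Cdh5 -0.38 and -0.89. The 21 endothelial markers had a median lineage difference of -0.10, at percentile 51.32 of random lists. Across genes, the lineage difference at sham correlated with the cell type difference after TAC at -0.099, and the lineage difference after TAC with the cell type difference at sham at -0.02. The lineage differences at the 2 surgeries correlated at 0.345. The standard deviation across genes was 0.233 for the mean lineage difference, beside 0.621 for TAC and 0.162 for the difference between responses. Errors shared by the arrays of 1 surgery stay in the TAC value and cancel in the other values.

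Among the lists, the median of 9 macrophage markers was higher in traced fibroblasts (0.37, percentile 99.98), with 8 of the 9 above 0 and 0 at least 2-fold higher at both surgeries, Cx3cr1 0.85 and 1.22 higher at the 2 surgeries and Laptm5 1.58 and 0.18 higher. Whether macrophage RNA in the traced samples contributes to the lineage differences of single genes was not tested. The median of 16 interferon response genes was lower (-0.28, percentile 0.04), with 1 of the 16 above 0 and 0 at least 2-fold lower at both surgeries, Rsad2 at -0.85 and -0.62. Also above the middle 95% of random lists were growth factors and receptors, other matrix, cardiogenic transcription factors, endocardial, mural and cardiomyocyte genes. Their medians were small, 0.06 to 0.11 (percentiles 98.4 to 99.89). In all, 8 lists lay outside the middle 95% for the mean lineage difference. The median of the proliferation list in traced minus untraced fibroblasts was 0.11 at sham (percentile 100), where 18 of 29 genes stood above 0, and -0.50 after TAC (below all random lists), where 1 of 29 did. The 4 members with the largest mean lineage differences, Cenpf, Pbk, Rrm2 and Bub1, were lower at both surgeries, unlike the list at sham, with Cenpf at -0.98 and -0.16 and Bub1 at -0.17 and -0.85. The untraced TAC array, which enters every lineage difference after TAC, stood apart in its controls, with 18S ribosomal RNA at 12.04 against 14.11 to 14.64 on the other arrays and a difference between 3′ and 5′ probe sets of Gapdh of 2.10 against 1.12 to 1.36. The TAC responses of traced and untraced fibroblasts differed at least 4-fold for 3 genes. In Cd24a, a surface glycoprotein gene, the TAC difference was 0.65 in traced and -1.53 in untraced fibroblasts, and in the ribosomal protein gene Rpl39l it was 2.37 and 0.30. The other gene has only a sequence number as its name. Of Cd24a, 2 other probe sets gave 0.31 and 0.33 in place of 1.09 for this contrast. The counts of this comparison are small, and 5 genes in place of 8 passed the lineage threshold after centring each array and 4 passed with the mean of all probe sets. In the other direction, 13 passed without a filter on dim genes and 82 at a 1.5-fold threshold.

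The fourth comparison asks how the endothelial cells of TAC mice differed from those of sham mice. The endothelial TAC array had far higher levels of matrix and fibroblast genes and of cell division genes than the endothelial sham array. The cytokine gene Il6 was 93.4-fold higher, the protease inhibitor gene Timp1 60.5-fold, Postn 46.7-fold, Col1a1 21.6-fold, the survival and mitosis gene Birc5 33.9-fold and the adhesion gene Sele, E-selectin, 25.7-fold. Of 11157 genes 1213 were at least 2-fold higher and 204 at least 2-fold lower, untested and on 1 array each. The same array also held more of 132 of 133 genes that lay below the median of the endothelial sham array, stood more than 4 log2 units higher in fibroblasts and differed by less than 0.5 with TAC in fibroblasts, with a median share of 6.42%. The share is the rise of a gene over the endothelial sham array as a percent of the excess of its fibroblast TAC intensity over that array, and its median was 4.9% net of the rise of 0.59 in genes matched on the endothelial sham level.

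The other genes with the largest differences were the microfibril genes Mfap4 (5.49) and Mfap5 (5.26), Serpina3n (5.26), Ltbp2 (5.18) and the cohesion gene Esco2 (4.82). Il6, Esco2 and Ptgs2 stood below the 10th percentile of the endothelial sham array, so their sizes rest on dim values. Lower after TAC were the interferon inducible gene Mndal, at 10.53 at sham and 2.99 after TAC, which is below the 10th percentile of that array (3.82), the retinoic acid hydroxylase gene Cyp26b1 (-2.96), Ecm2 (-2.62), the phospholipase gene Pla2g7 (-2.52), Zbtb16 (-2.49), Orly (-2.44), Speer8-ps1 (-2.41), Astx3 (-2.38), the interferon inducible GTPase gene Iigp1 (-2.19) and Nlrc5 (-2.17), an activator of MHC class I genes. Another probe set of Mndal gave -7.33 in place of -7.54. Since sham and TAC cells come from different mice, differences between the mice themselves, such as genotype, cannot be told from TAC for these genes. Of 29 proliferation genes 28 were at least 2-fold higher (median 3.75, percentile 100), with Top2a at 4.54, Rrm2 at 4.36 and Ccnb2 at 4.35. In 28 of these 29 genes the endothelial TAC level lay above the mean fibroblast TAC level. After TAC endothelial cells held the selectin genes Sele (4.68) and Selp (2.63) and the tip cell gene Apln (2.24) at higher levels, as well as Plvap (3.57) and Esm1 (1.49).

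Of 30 other matrix genes 27 were at least 2-fold higher (median 3.05), of 20 fibroblast markers 19 (median 2.78) and of 18 collagen and crosslinking genes 13 (median 2.60), each above all random lists. Beside the median share of 6.42% over the 133 fibroblast genes, the share was 18.04% for Lum, 8.4% for Tcf21 and 5.4% for Pdgfra, and 50.6% for Col1a1, 52.8% for Col1a2, 63.4% for Col3a1 and 47.0% for Postn, each with the endothelial sham intensity subtracted. The median and the 90th percentile of the share, as percents of the fibroblast TAC intensity, were then taken off the endothelial TAC array, an alternative chosen after seeing the data. The rest was not scaled back up. If the share is fibroblast RNA, a gene unchanged in endothelial cells would therefore land somewhat below 0. With the median share of 6.42% the medians over the same genes were 2.21 for other matrix, 2.04 for fibroblast markers, 1.76 for collagen and 3.69 for proliferation, and with the 90th percentile of the share, 11.75%, they were 1.01 for other matrix, 0.66 for fibroblast markers, -0.21 for collagen and 3.64 for proliferation. Over the genes still detected after the 90th percentile share they were 1.93, 1.54, 0.85 and 3.64. At least 2-fold higher were 805 genes with the median share and 591 with the 90th percentile share, in place of 1213. The medians were 1.77 for mesenchymal transition (S100a4 3.69, Sox9 3.24, Twist1 2.33), 1.30 for cytokines (Ptgs2 3.76, Cxcl2 2.19), 1.05 for proteases, 0.79 for TGF-beta response (Inhba 3.26, Ccn2 3.13) and 0.83 for macrophage markers (Ctss 1.96, Csf1r 1.74), each at percentile 99.6 or above. With the median share taken off, these medians over the same genes were 0.62, 0.43, 0.76, 0.34 and 0.77. With the 90th percentile share they were -0.15, -0.14, -0.08, -0.10 and 0.72, and over the genes still detected 0.07, 0.37, 0.22, -0.06 and 0.72.

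Lists of endothelial function differed in direction. The 25 endothelial markers had a median of -0.25 (below all random lists), with Rgcc at -0.82, Sox17 at -0.59, Cdh5 at -0.29, Tek at -0.25 and Pecam1 at -0.12. The 12 genes in the list of capillary fatty acid handling had a median of -0.57, and 0 stood above 0. The 3 at least 2-fold lower were Timp4 (-2.08), Fabp3 (-1.13) and Car4 (-1.06). Timp4 is also in the list of proteases and inhibitors, and Car4 is a carbonic anhydrase. These values alone do not show a fall of fatty acid handling. The median of 11 arterial genes was -0.03 (percentile 11.24), that of 17 genes of angiogenesis was 0.15 (percentile 56.54) and that of 6 adhesion genes was 0.73 (percentile 97.6). The 11 cardiomyocyte genes had a median of -1.09, with Pln at -2.07 and Mb at -1.40, and 12 mural markers a median of -0.53. The 15 interferon response genes had a median of -0.27 (percentile 0.14), with Gbp3 at -0.86 and Stat2 at -0.84. Acta2 stood 2.01-fold lower in endothelial cells after TAC. In all, 18 of 34 lists lay outside the middle 95% of their random lists.

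**Figure D3:**
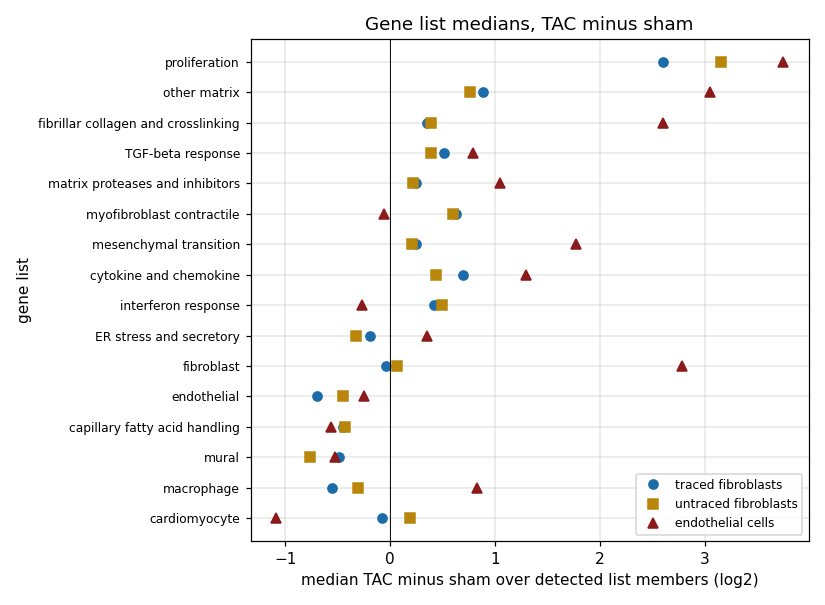
Median TAC minus sham difference over the detected members (horizontal axis, log2) of 16 of the 38 gene lists (vertical axis) in traced fibroblasts, untraced fibroblasts and endothelial cells, each point the median of 1 list in 1 population, with no error bars because each group has 1 array. The proliferation list stands far above 0 in all 3 populations, while the fibroblast list stands at 2.78 in endothelial cells and near 0 in both fibroblast populations.

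The last comparison asks which TAC differences were common to all 3 populations. At least 2-fold higher in all 3 were 27 of 29 proliferation genes, among them Top2a and Birc5, 12 of 30 other matrix genes, among them Tnc and Cthrc1, and 5 of 21 cytokine genes, among them Il6. Zbtb16 was at least 2-fold lower in all 3. The counts were 285 genes higher and 24 lower, against shuffled means of 61.8 and 5.5 and highest shuffled counts of 89 and 13. Differences between the mice or their processing that the populations share would exceed the shuffles too. Of the 503 genes higher in both fibroblast populations 403 were detected on the endothelial arrays, and 267 of these were also at least 2-fold higher there and 2 at least 2-fold lower. Of the 285 genes, 13 were not detected on the endothelial arrays and 5 not on the fibroblast arrays, and of the 24 lower genes 4 and 4, as the count asks for detection on any of the 6 arrays. Of the 208 lower genes 113 were detected, and 16 were at least 2-fold lower and 12 at least 2-fold higher. The mean fibroblast and the endothelial TAC differences correlated at 0.466 across 12257 genes. With the median and the 90th percentile of the fibroblast share taken off the endothelial TAC array, 244 and 208 genes were higher in all 3 and 51 and 77 lower.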

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

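The tests of explanations in this part were all chosen after the results were seen, and the arrays have no replicates.

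In the endothelial cells 5 genes that the report's rule names moved with TAC in the opposite direction to both fibroblast populations, and these differences between populations were not tested. Scara5 was 2.28 higher in endothelial cells and -2.01 and -1.34 in traced and untraced fibroblasts, Pgf was 1.75 higher against -1.67 and -1.97, and Cxcl14 was 1.17 higher against -1.54 and -2.01. Scara5 and Cxcl14 are higher in fibroblasts than in endothelial cells and had shares of 4.5% and 5.8% on the endothelial TAC array, as a rise over endothelial sham, beside the median of 6.42% over the 133 fibroblast genes weighed below. Acta2 was -1.0 against 1.44 and 1.25, but its mean in fibroblasts was -0.215 without probe sets of doubtful specificity and 0.297 with the mean of all its probe sets, so the opposite direction rests on 1 doubtful probe set. Chac1 was -1.3 against 1.59 and 1.35. The median of the interferon response list was -0.27 in endothelial cells against 0.42 and 0.49 in the fibroblasts, and this difference was not tested either.

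The spike-in control bioB was 2.18 higher on the endothelial arrays than on the fibroblast arrays. The control bioC stood at 12.66 and 12.48 on the endothelial arrays against 11.34 to 12.07 on the fibroblast arrays. For bioD these were 14.19 and 14.09 against 13.76 to 14.01. This technical difference runs along with cell type and cannot be separated from it in the comparison of fibroblasts with endothelial cells. A group of 74 probe sets, 21 of them with 1 gene symbol and 53 without, was higher on the traced sham and endothelial sham arrays than on the other arrays, while 19 were lower on both.

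Genes of fibroblasts stood higher on the endothelial TAC array than on the endothelial sham array. Matrix genes rising alone in endothelial cells are argued against by the 122 set genes outside the matrix, protease and fibroblast lists, whose median share was 6.18%, and 3.48% net of the highest rise of genes matched on their endothelial sham level. The 11 set genes in those lists had a larger median share, 10.25%, and 9.66% net. Across the set the log of the share correlated with the fibroblast TAC level at 0.54. The share was thus not even across the set, and the cause of this was not tested. Scaling of that array as the whole cause is argued against by the set of 133 genes standing 1.15 above genes matched on their endothelial sham level, whose own median was 0.59 with a highest draw of 0.91. Fibroblast RNA in the endothelial TAC sample stays open: net of the median and of the highest rise of the matched genes, 90.2% and 79.7% of the set had a share of 1% or more, which is above and below the 90% that this explanation was taken to need, and for 66.9% and 86.5% of the set the median and the highest rise alone give such a share. The matched genes were chosen by their endothelial sham level and may hold fibroblast RNA too. Net shares may then be too low, so these values cannot decide. Endothelial cells that gained the whole fibroblast profile would give the same shares and stay open, untested, as do the further shares of Col1a1, Col3a1 and Postn at 50.6%, 63.4% and 47.0%.

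Proliferation genes stood higher on the same array. Fibroblast RNA as their whole source is argued against by 96.6% of the 29 genes standing above their mean fibroblast TAC level, which no share of fibroblast RNA reaches. Division of endothelial cells after TAC stays open as a biological explanation, and RNA from another dividing cell type was not tested.

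The Rosa26 transcript stood higher in traced fibroblasts. Endothelial RNA in the traced samples is argued against by the endothelial list, whose larger median in traced minus untraced fibroblasts was -0.08, while the Rosa26 difference would need 45.8% endothelial RNA at sham and 67.0% after TAC. Recombination by Tie2-Cre of a reporter at this locus may explain it, and the endothelial arrays stood at least 2.23 above the untraced fibroblast arrays. A difference in Rosa26 transcription between the cell types without recombination would give this too, so the value cannot decide. The labels do not give the reporter, so recombination stays a hypothesis.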

How the results depend on the processing

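The share subtractions, each fibroblast population alone and each surgery alone were chosen after seeing the data, and the other alternatives were planned. Of 133 alternative counts and correlations 95 stayed within the limits and 38 moved, of 652 list medians 498 stayed, 149 moved and 5 reversed, and of 4263 values of named genes 3824 stayed, 232 moved, 130 became stronger, 54 weaker and 23 reversed. The limits were a factor of 1.5 for counts and a change of 0.1 for correlations. These limits are wide: with repeated quantile normalization 1045 genes were higher and 306 lower in endothelial cells after TAC, in place of 1213 and 204. Both counts were scored as staying. By replicate number, no paired analysis was possible because each group has 1 array, so the groups share only 1 number. The surgery that cell types share was fitted as a block, and TAC against sham with the populations as blocks was not run, since populations of 1 surgery that come from the same hearts would not be replicates. Where no cause follows from the construction of an alternative, the cause was not tested. The arrays limit the results through their number and through dim probe sets: probe sets of the same gene correlated at 0.78 for TAC in fibroblasts and 0.71 in endothelial cells, but at 0.28 for lineage and 0.27 for the difference of responses, across 6176 genes, which are not independent replicates.

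For fibroblasts against endothelial cells, the counts higher in fibroblasts were 2211 with 4 arrays against 2 and 2298 with surgery as a block. Leaving out each array gave 685 to 1715 genes higher in fibroblasts and 472 to 817 in endothelial cells. Leaving out an endothelial array leaves a lone one that is assumed to vary like the fibroblasts. The lowest of both counts came without the endothelial sham array, but the highest in fibroblasts came without the endothelial TAC array. The assumption, which both fits share, therefore does not account for the low counts by itself.

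A fold threshold of 1.5 gave by its construction more genes: 1035 higher and 565 lower in both fibroblast populations, 620 and 143 in all 3 populations, 82 by lineage, 2746 and 852 in endothelial cells, and 69 for the difference of responses. A threshold of 3 gave 268 and 62, 158 and 3, 0, 533 and 44, and 0. With genes above the upper quartile, so with fewer genes, 256 were higher in both fibroblast populations, 3 differed by lineage, 618 were higher and 132 lower in endothelial cells, and 1 differed in response, while without a filter 13 differed by lineage and 7 in response. By lineage, 5 genes passed the threshold after centring and 4 with the mean of all probe sets, and with fewer conditions to meet 90 passed on sham arrays alone and 55 on TAC arrays alone. In untraced fibroblasts alone 343 genes were lower after TAC.

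With the median fibroblast share taken off the endothelial TAC array 805 genes were higher and 314 lower there, and 51 were lower in all 3 populations. With the 90th percentile share these were 591, 530 and 77. Of the list medians outside the middle 95% of random lists, those that changed sign were the endothelial list in fibroblasts (0.584, upper quartile) and, in endothelial cells, Wnt without a filter (-0.022), and with the 90th percentile share, over genes still detected, TGF-beta response (-0.058), Wnt (-0.519) and endocardial (-0.016), which stayed above 0 with the median share (0.327, 0.731 and 2.266). In the main setting TGF-beta response, Wnt and endocardial stood at 0.788, 1.489 and 2.364. The subtraction did not scale the rest back up, so unchanged genes can land below 0, which also adds to the counts of lower genes. The values of -0.058 and -0.016 therefore do not show a fall. Lists inside the middle 95% also changed sign with the shares, such as cardiogenic (-0.38) and growth factors (-0.09) with the 90th percentile share.

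Of the named genes with at least a 2-fold difference, Acta2 in fibroblasts reversed to -0.215 without probe sets of doubtful specificity. The other reversals are endothelial TAC differences pushed below sham by the subtraction itself. With the median and the 90th percentile share they were -0.468 and -4.038 for Pdgfra, -1.278 and -2.824 for Pdpn, -1.289 and -3.605 for Fap, -0.510 and -2.959 for C1ra, and -0.694 and -2.939 for Igfbp6. With the 90th percentile share alone they were Aldh1a2 (-2.192), Nox4 (-0.671), Mmp23 (-2.701), Serping1 (-0.364), Frzb (-0.710), Sfrp2 (-1.269), Ccn5 (-2.151), Tbx20 (-0.172), Sox9 (-0.018), Tcf21 (-2.933), Twist1 (-1.325) and Cdh2 (-1.511).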

Other observations

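The values of this part are given without an explanation, and the count of genes restricted to endothelial cells was chosen after the fibroblast share had been seen. The report does not describe the following list medians. In fibroblasts after TAC, 25 growth factor and receptor genes had a median of -0.21 (percentile 0.25), with Igfbp3 at -1.74 and Fgf10 at -1.71 but the growth factor gene Pdgfc at 2.69, and 14 Notch and BMP genes had a median of -0.48 (below all random lists), with Gdf10 at -2.15 and Notch4 at 2.24. In endothelial cells after TAC, 17 hypoxia and glycolysis genes had a median of 0.55 (percentile 99.12), with Egln3 at 2.08 and Pgk1 at 1.64. Inside the middle 95% of random lists lay 17 ribosomal protein genes (-0.06 in fibroblasts, percentile 13.4, and 0.25 in endothelial cells, percentile 85.28), 22 oxidative phosphorylation genes (0.06, percentile 75.81, and 0.31, percentile 91.36) and 7 Hox genes (0.11, percentile 66.92, and -0.13, percentile 43.78).

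On the fibroblast arrays Mndal stood at 8.32 and 8.56 at sham and at 6.39 and 6.85 after TAC. The 18S ribosomal RNA control stood at 12.04 on the untraced TAC array, -2.14 from the mean of the other fibroblast arrays, and the Gapdh difference between 3′ and 5′ probe sets was 2.10 there and between 1.12 and 1.36 on the other arrays. In the opposite direction to the fibroblast share, genes restricted to endothelial cells did not stand higher after TAC on the fibroblast arrays: 30 of 59 were higher on the traced and 23 of 49 on the untraced array, with medians of 0.04 and -0.04.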
